A study of Mus musculus with 16 samples.

How the data were processed

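RNA from the whole brain of 16 C57BL/6 mice was sequenced, with 1 library per mouse and 4 mice in each of 4 groups. Pregnant dams were injected intraperitoneally with lipopolysaccharide (LPS) or saline on gestation day 16. Their offspring, described as male, were injected with LPS or saline at postnatal day 30, and brains were collected at postnatal day 32. Each group name holds a pair of injection words, and these were read in the order of the treatment protocol, the dam's injection first. The labels do not spell this order out. If it were the reverse, the names prenatal and pubertal would swap throughout, while the interaction would stay as it is. Litters are not given, so mice of 1 group, or of groups with the same prenatal injection, may share a dam. The p-values measure the spread between these mice.

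The deposited files hold whole-number read counts per Ensembl gene, which the authors made with STAR 2.5.2b and HTSeq 0.11.2 on GRCm38, per the submitters' processing notes. The strand setting, the annotation release and any read filter are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart. Reads with several best alignments were counted apart from genes, so genes with near-identical copies (H2-Q4, H2-Q6 and H2-Q7, other class I genes, ribosomal proteins) carry uncertain counts. Each file lists 49671 genes and 5 special entries, which were left out of library sizes and tests. Of all counts, special entries included, 8.38 to 11.1% were reads without a gene, 5.11 to 5.48% were ambiguous and 3.18 to 3.90% did not align uniquely. Gene totals ran from 25729919 to 38571036 counts per library with a median of 31810000. Reads carried no molecular identifiers, so the floor of 1 read covers counting error only, while SDs and standard errors include the spread between mice. Symbols and GRCm38 coordinates came from GENCODE release M21, in which 49412 identifiers were matched and 259 were not.

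Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 18875 genes, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation held the 4 groups and all 16 libraries, so that the groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over the tested genes, two-sided, with a threshold of 0.05. The biological coefficient of variation was 10.4%. There were 8 comparisons: 5 between pairs of groups, the interaction, and the effect of each injection averaged over the other. Of 40 gene lists, 39 had enough tested members and were tested with camera of limma 3.58.1, with the correlation between genes estimated for each list and adjustment over the lists within a comparison.

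The comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined. For pairs of groups the rule takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups. It adds up to 4 members with the smallest p from each biological list with a call, and always Il1b, Tnf, Il6, Lcn2, Gfap and Aif1. For the interaction and the averaged comparisons it takes up to 10 genes per direction by p, and where nothing is called the 3 genes with the smallest p are given as values. Predicted genes and pseudogenes were counted and, except among those 3, not named. The result of 1 gene that the rule takes is not reported here.

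On simulated counts with 200 changed genes, the test of prenatal LPS before pubertal LPS recovered 76% of genes changed by 1 log2 unit and 55% of those changed by 0.5, with 4.38% false calls. For pubertal LPS after prenatal saline it recovered 77% and 63% with 6.67% false calls, for the interaction 65% and 22% with 6.45%, and for the averaged prenatal comparison 91% and 71% with 6.9%. In the simulated list test the raised list was recovered and 0 of the unchanged lists were called. The simulation drew each gene independently around a mean common to all libraries. It held none of the cerebellar, GC, length or replicate structure of the real libraries, so these rates may not hold for them.

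Replicate numbers come from the labels. Deviations from group means over 12418 genes correlated between same-numbered libraries at 0.187 to 0.649 for prenatal LPS before pubertal saline, 0.295 to 0.400 for prenatal LPS before pubertal LPS and 0.213 to 0.358 for pubertal LPS after prenatal LPS. By a rule that every same-numbered pair correlates over 0.1, the numbers were taken to pair the libraries of these 3 comparisons. Only 10 of 16 libraries correlated best with their own number, so the pairing is not certain. Adjusted p-values come from the fit without a block. The fit with the replicate number as a block is given beside these comparisons where it moves a count. No libraries of the same group were duplicates: counts within groups differed by a chi-square of 4.91 to 33.5 per degree of freedom over 24 pairs. Pairs between groups were not checked.

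Alternatives were RLE size factors, other low-count filters, the Wald test of DESeq2 1.42.0, the replicate block, 1 surrogate variable from sva 3.50.0, fits on the compared groups alone and leaving out each library. Added after seeing the data were a covariate for cerebellar transcripts, a spline correction of each library for GC content and exonic length (values known for 99.7% of genes), their combinations, and fits within libraries split at 1 CPM of Gabra6. The correlation of the myelin mean with the thalamus and midbrain mean was also added then, with a permutation test that shuffled libraries within groups.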

Results

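Messenger RNA levels were measured by RNA sequencing in whole brains of 16 mice that differed in exposure to LPS, a cell-wall component of Gram-negative bacteria that triggers innate immune signalling. The 4 groups of 4 mice were saline-saline, LPS-saline, saline-LPS and LPS-LPS, the dam's injection on gestation day 16 named before the offspring's at postnatal day 30. This order is a reading of the labels. Libraries held 25729919 to 38571036 gene counts, both extremes in LPS-saline, so that 1 read stood for at most 0.0389 CPM. Values below are library-scaled counts (CPM) as mean ± SD of 4 mice, and log2 fold changes with standard errors from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

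The libraries differed in ways that the groups do not name. Gabra6, a receptor subunit of cerebellar granule cells, lay under 1 CPM in 8 libraries, which occurred in each of the 4 groups (saline-saline 1, 2 and 3, LPS-saline 1 and 2, saline-LPS 1 and 2, and LPS-LPS 2), and at 2.51 to 70.4 CPM in the other 8. The first principal component, with 20.6% of the variance, ran from 1.33 to 32.5 in the former and from -25.3 to 4.92 in the latter. In LPS-LPS replicate 3, Xist, the RNA of the inactive X chromosome, stood at 503 CPM and the Y-linked Ddx3y at 0 CPM, although all offspring were described as male. These values argue against a male source of this library. The pituitary hormone Gh reached 502.5 CPM in LPS-LPS replicate 1 and 44.1 CPM in saline-LPS replicate 1.

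**Figure D1:**
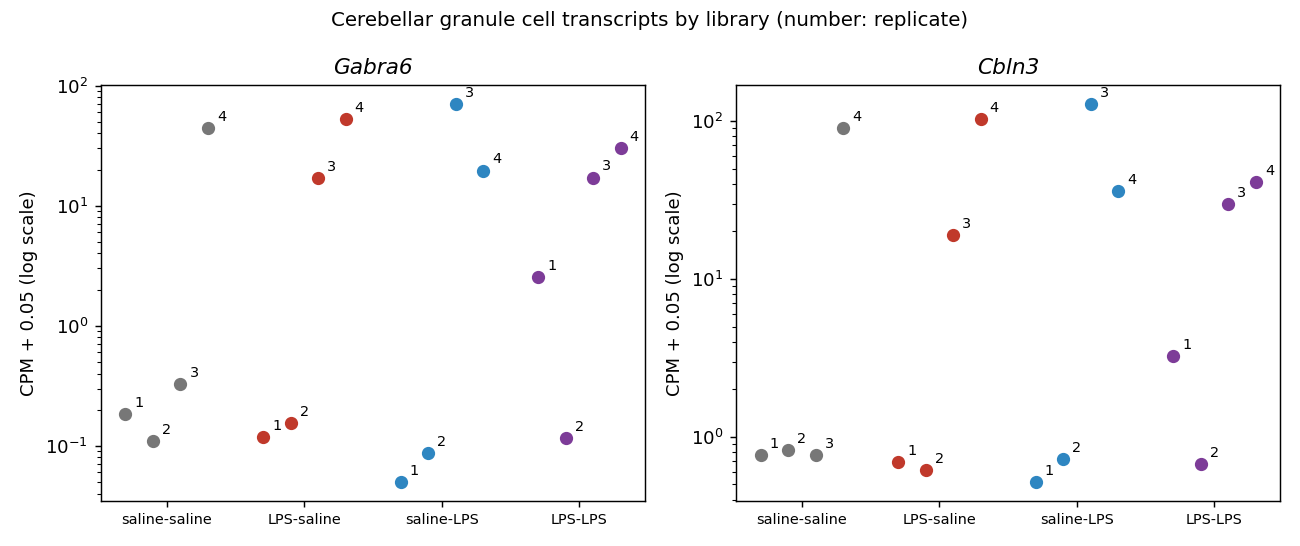
CPM of the cerebellar granule cell genes Gabra6 and Cbln3 (log axis, 0.05 added) in each library by group, with the replicate number beside each point. In 8 libraries Gabra6 lay under 1 CPM, and the mean of Cbln3 there was 0.65 CPM against 56.3 CPM in the other 8.

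Prenatal LPS before pubertal saline asked whether the dam's injection alone was followed by a difference in the adolescent brain. Genes of antigen presentation on MHC class I rose. H2-K1, a class I heavy chain (chromosome 17, 33996017 to 34000347), was at 63.5 ± 13.2 CPM in LPS-saline and 33.0 ± 3.47 CPM in saline-saline (log2 0.95 ± 0.13, adjusted p = 0.00388). B2m, the shared light chain (chromosome 2, 122147686 to 122153083), was at 86.7 ± 7.71 against 58.3 ± 2.67 CPM (log2 0.57 ± 0.07, adjusted p = 0.000929). Lyz2, a lysozyme of myeloid cells, was at 11.96 ± 0.974 against 6.55 ± 0.29 CPM (log2 0.87 ± 0.11, adjusted p = 0.000929). Tspan2 and Mal, both of myelinating oligodendrocytes, fell by 0.47 and 0.39 on the log2 scale (adjusted p = 0.0258 and 0.0427).

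By list, 6 of 18 tested MHC class I genes rose (13 adjusted over the list alone), and this list was called by camera with an estimated correlation (adjusted p = 0.0264). H2-D1 rose by 0.67, H2-Q4 by 1.05, H2-Q6 by 1.72 and H2-Q7 by 1.81 on the log2 scale, the H2-Q genes with shared reads. Of 46 interferon-stimulated genes 4 rose (9 adjusted over the list alone): Ifi27l2a (2.82-fold), Irf7, a transcription factor of the interferon response (log2 1.07), Ifitm3 (0.62) and Ifi27 (0.56), with an adjusted p of 0.261 for the list. Complement had 2 of 21 higher (8 higher and 1 lower adjusted over the list alone), C1qb (0.51) and C1qa (0.54), with a list adjusted p of 0.229. Among 29 microglia activation genes Lyz2 and Fcgr3, an Fc receptor, rose (11 adjusted over the list alone; list adjusted p = 0.175), and of 20 homeostatic microglia genes Trem2, a microglial lipid receptor, rose by 0.51 (2 adjusted over the list alone; list adjusted p = 0.447). Ctss, a lysosomal protease that acts in MHC class II presentation, rose by 0.61 as 1 of 10 class II genes (list adjusted p = 0.233). In the myelin list 2 of 24 fell (9 adjusted over the list alone; list adjusted p = 0.233), and the mean of thalamus and midbrain genes differed by -0.198 (exact permutation p = 0.143, 0.46 adjusted). The mean of 13 border macrophage and monocyte genes was higher by 0.232 (exact permutation p = 0.0286, 0.234 adjusted; list adjusted p = 0.291), with 0 called, and by 0.21 in saline-LPS against saline-saline.

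The acute-phase gene Saa3 stood at 1.22 ± 1.17 CPM (163 counts in the group) against 0.0473 ± 0.0632 CPM (7 counts; adjusted p = 0.0389). Arrdc3, Secisbp2l and Plekha1 fell by 0.43, 0.29 and 0.27. Lcn2, an acute-phase protein of glia and vessels, had a log2 value of 1.34 ± 0.39 without passing (adjusted p = 0.122), as did Gfap, the astrocyte filament (0.26, adjusted p = 0.101), and Aif1, a microglial marker (0.37, adjusted p = 0.232). In all 34 genes were called, 28 higher and 6 lower, with a median fold of 1.44. With the replicate number as a block 409 were called, and with the correction for GC content and length 23, of which 15 were higher and 8 lower and 16 were shared. The count fell to 7 without saline-saline replicate 4 and rose to 391 without saline-LPS replicate 1.

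**Figure D2:**
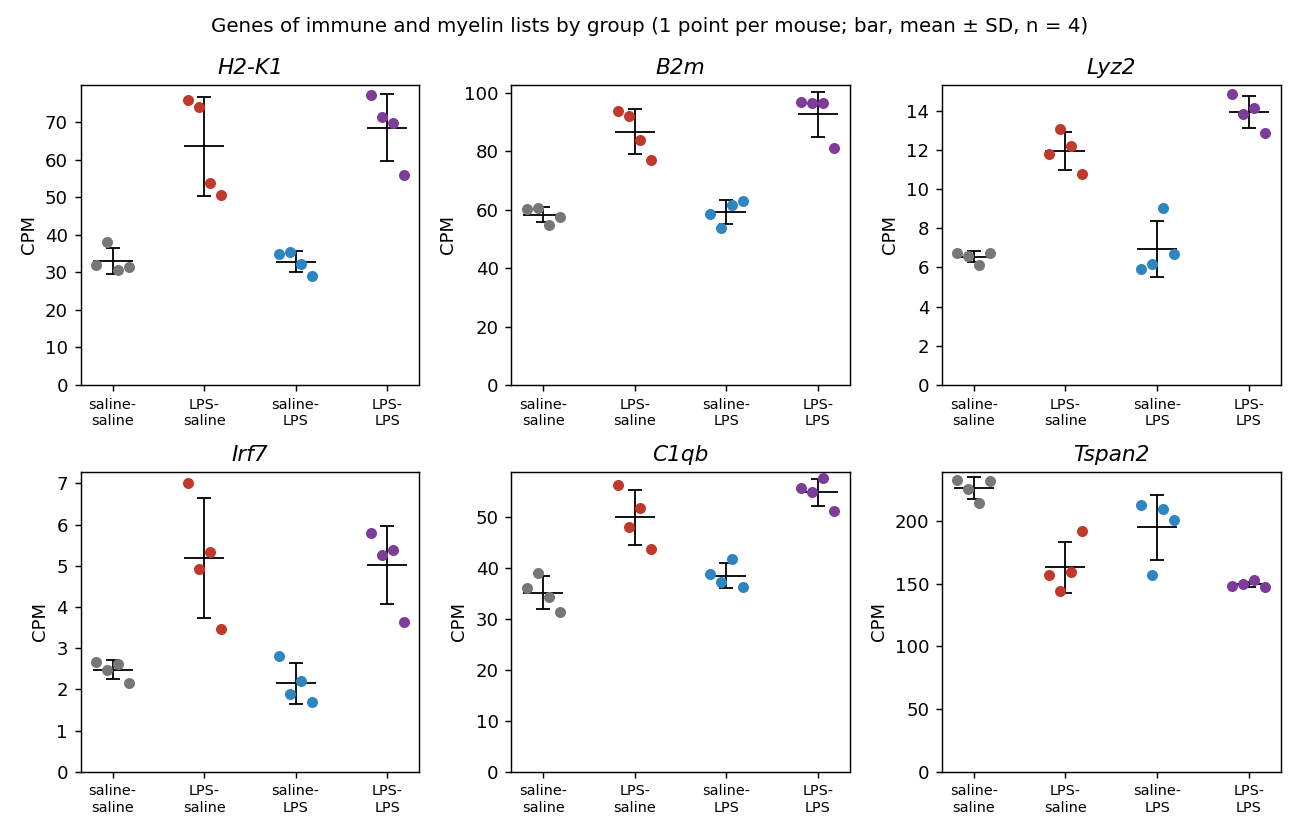
CPM of H2-K1, B2m, Lyz2, Irf7, C1qb and Tspan2 in each mouse (points) by group, with the mean and SD of 4 mice (bars). H2-K1 averaged 63.5 and 68.5 CPM in the groups with prenatal LPS and 33.0 and 32.8 CPM in those with prenatal saline.

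Prenatal LPS before pubertal LPS asked the same in offspring that received LPS at postnatal day 30, with none of the libraries used above. The class I genes were again higher: H2-K1 at 68.5 ± 8.94 against 32.8 ± 2.88 CPM (log2 1.06 ± 0.13, adjusted p = 0.000913), B2m at 92.7 ± 7.67 against 59.1 ± 4.08 CPM (log2 0.65 ± 0.07, adjusted p = 7.58e-05) and H2-D1 with log2 0.75. H2-Q6 and H2-Q7 had log2 values of 2.75 and 2.60 with shared reads. Lyz2 rose by 1.00 ± 0.11 (adjusted p = 7.58e-05), Irf7 by 1.22, Snx20 by 1.12 and Fam181a by 0.97, and Ifi27l2a was 2.83-fold higher. C3, the central complement protein, rose by 1.13. Saa3 stood at 1.37 ± 0.497 CPM (168 counts) against 0.0234 ± 0.0469 CPM (3 counts; adjusted p = 0.0154).

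The MHC class I list was called, with 7 of 18 higher (15 adjusted over the list alone; adjusted p = 0.0213 with an estimated correlation). Of the interferon-stimulated genes 4 of 46 rose, Bst2 (0.78) and Ifi27 (0.50) among them (11 adjusted over the list alone; list adjusted p = 0.417). Of complement 4 of 21 rose, C1qa, C1qb and C1qc by 0.50, 0.51 and 0.54 (5 adjusted over the list alone; list adjusted p = 0.386). Lyz2, Fcgr3 (0.58) and Ctsz, a lysosomal protease (0.35), rose among microglia activation genes (8 adjusted over the list alone; list adjusted p = 0.173), and Trem2 and its adaptor Tyrobp among homeostatic ones (5 adjusted over the list alone; list adjusted p = 0.545). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 0.45 as 1 of 26 (list adjusted p = 0.828). Genes that fell included Tspan2 by 0.38, Tsc22d3, a glucocorticoid-induced gene, by 0.35, Plat, a plasminogen activator, by 0.32, Heph, a copper-dependent ferroxidase, by 0.53, and Rybp, Ubap1l, Dusp11, Acap2 and Lrrc58 by 0.41, 0.48, 0.32, 0.32 and 0.24. Lcn2 (1.01), Gfap (0.19) and Aif1 (0.47) did not pass, with adjusted p of 0.25, 0.238 and 0.129.

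In all 115 genes were called, 106 higher and 9 lower, with a median fold of 1.30. With the replicate block 326 were called, with the GC and length correction 37, of which 28 were shared, and without LPS-LPS replicate 3, the library with Xist, 22. Of the genes called in this comparison and the preceding one, 19 were higher in both, 1 was lower in both and 0 were opposite. If the calls were independent, 0.157 would be shared as higher. They were not independent, since both came from 1 fit that shared each gene's estimate of the spread. Both sets of log2 fold changes also fell with exonic length (Spearman -0.474 here and -0.507 in the preceding comparison). Across all tested genes, which are not independent replicates, the log2 fold changes correlated at r = 0.338 (Spearman 0.443), and at 0.315 and 0.382 after the correction.

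Averaged over the pubertal injection, prenatal LPS compared 8 mice with 8. Lyz2 was at 12.9 ± 1.34 against 6.75 ± 0.973 CPM and B2m at 89.7 ± 7.8 against 58.7 ± 3.22 CPM (log2 0.94 ± 0.08 and 0.61 ± 0.05, adjusted p = 7.05e-07 for both). H2-K1 rose by 1.00 ± 0.09 (adjusted p = 1.36e-05), C1qb by 0.51 ± 0.06 (adjusted p = 1.89e-05), and H2-D1, H2-Q4, H2-Q6, H2-Q7, Ifi27l2a and Irf7 were the other leading rises. Lcn2 (log2 1.18), Gfap (0.22), Aif1 (0.42) and Serpina3n (0.39) passed here with adjusted p of 0.0145, 0.0116, 0.0128 and 0.00326. Among genes that meet the rule for naming, the leading falls were Tspan2 (log2 -0.43 ± 0.06, adjusted p = 0.000478), Acap2, Mal, Tsc22d3, Rybp, Plekha1, Secisbp2l, Arrdc3, Gpr155 and Ccp110. Slc1a2, the main astrocyte glutamate transporter, and Gjb6, a connexin, fell by 0.22 and 0.19 among 3 of 18 homeostatic astrocyte genes (4 adjusted over the list alone; list adjusted p = 0.469).

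Of 18 MHC class I genes 12 rose, all 18 when adjusted over the list alone, and the list was called (adjusted p = 0.0194 with an estimated correlation). Rises numbered 14 of 46 interferon-stimulated genes (16 adjusted over the list alone; list adjusted p = 0.248) and 7 of 21 complement genes (10 higher and 2 lower adjusted over the list alone; list adjusted p = 0.229). They numbered 11 of 29 microglia activation genes (15 higher and 1 lower adjusted over the list alone; list adjusted p = 0.135) and 6 of 20 homeostatic microglia genes (8 adjusted over the list alone; list adjusted p = 0.442). Of 24 myelin genes 8 fell (14 adjusted over the list alone; list adjusted p = 0.248), while the centred mean of thalamus and midbrain genes was -0.0593 in LPS-saline and -0.0905 in LPS-LPS against 0.139 in saline-saline and 0.011 in saline-LPS. In all 1476 genes were called, 924 higher and 552 lower, with a median fold of 1.16. Values of the groups of 8 did not overlap for 171 genes, 0.906% of those tested, where chance gives 0.0155% for a single gene. The correlation of a library's deviations with exonic length did not overlap between these groups either. It ran from -0.46 to -0.0744 after prenatal LPS and from -0.0515 to 0.434 after prenatal saline. Genes that follow this trend move together, so it may account for part of the 171. With the GC and length correction 639 were called, 457 of them shared. Within the libraries under 1 CPM of Gabra6 27 were called (26 shared), within those at 1 CPM or more 996 (615 shared), and without LPS-saline replicate 1 700.

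**Figure D3:**
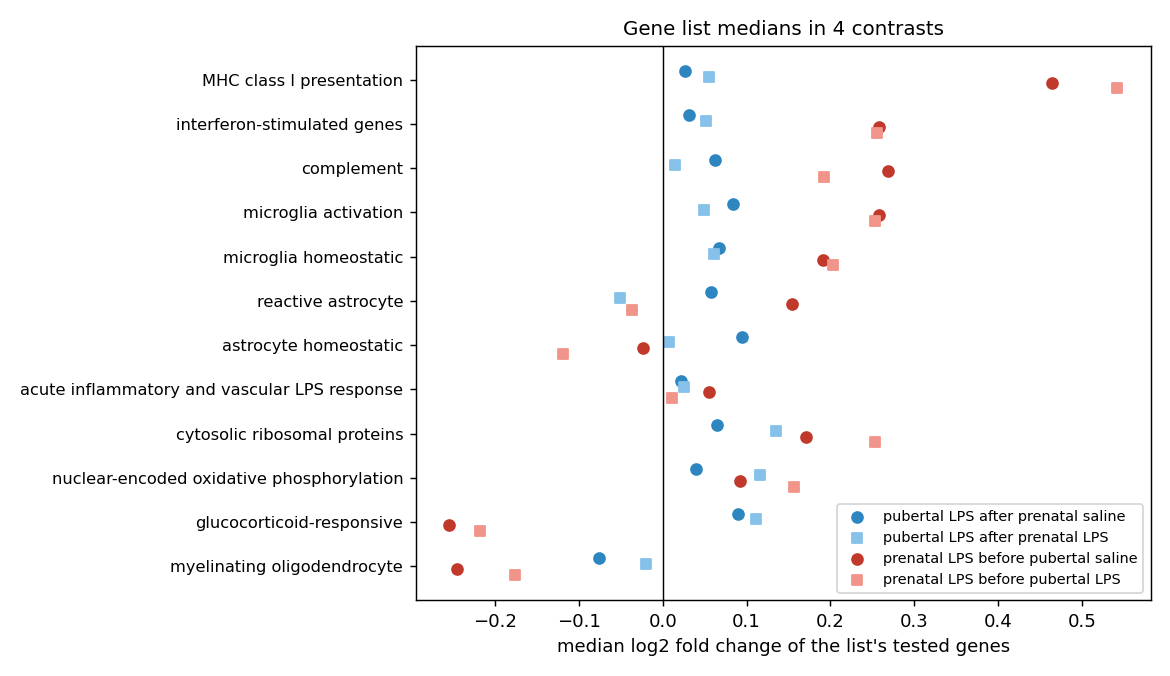
Median log2 fold change of the tested members of 12 gene lists (vertical axis) in 4 comparisons (colours and shapes). The MHC class I list had medians of 0.46 and 0.54 in the comparisons of prenatal LPS.

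Both exposures against none gave more calls than the other pairs of groups. Lyz2 was at 13.9 ± 0.818 in LPS-LPS against 6.55 ± 0.29 CPM in saline-saline (log2 1.09 ± 0.11, adjusted p = 4.35e-05), H2-K1 rose by 1.06 ± 0.13 (adjusted p = 0.000729) and B2m by 0.67 ± 0.07 (adjusted p = 6.59e-05). Ifi27l2a was 2.82-fold higher, and H2-Q7, H2-Q6, C3, Foxc2, Irf7 and the small RNAs Rn7sk and Snord104 had log2 values of 1.77, 1.65, 1.11, 1.07, 1.02, 1.60 and 1.02. Among genes that meet the rule for naming, the largest falls were Onecut2 (log2 -0.97 ± 0.16, adjusted p = 0.00242), Plekhg1 (-0.94), Kcne4, a potassium channel subunit (-0.91), Prox1, a transcription factor of dentate granule neurons (-0.86), Plekhh1, Shisa6, Sec14l5, Atp10b, Drd5, a dopamine receptor (-0.71), and BC065397. Tspan2 fell by 0.60, Mal by 0.50, Gjc3 by 0.49 and Ermn by 0.65, all of myelin, and Enpp6, of newly forming oligodendrocytes, by 0.57.

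The MHC class I list had 10 of 18 higher (16 adjusted over the list alone; adjusted p = 0.0534 with an estimated correlation, and 0.0319 to 0.0558 over other settings of the same test). Rises numbered 9 of 46 interferon-stimulated genes (16 adjusted over the list alone; list adjusted p = 0.422) and 5 of 21 complement genes (8 higher and 1 lower adjusted over the list alone; list adjusted p = 0.356). They numbered 8 of 29 microglia activation genes, such as Ctsd and Apoe (14 higher and 1 lower adjusted over the list alone; list adjusted p = 0.151), and 4 of 20 homeostatic microglia genes, Aif1 among them (6 adjusted over the list alone; list adjusted p = 0.48). Means of other cell types were higher too, by 0.315 for border macrophages and monocytes and 0.336 for meninges and fibroblasts (each exact permutation p = 0.0286, 0.234 adjusted). The lymphocyte mean was higher by 0.348 (exact permutation p = 0.0571, 0.367 adjusted). Gfap rose by 0.33 (adjusted p = 0.0103) and Serpina3n by 0.43, while Lcn2 had 1.20 (adjusted p = 0.0726). Of 24 myelin genes 6 fell (11 adjusted over the list alone; list adjusted p = 0.422). The mean of thalamus and midbrain genes was lower too (-0.229, exact permutation p = 0.0286, 0.234 adjusted), and in deviations from group means over the 16 libraries it correlated with the myelin mean at r = 0.792 (permutation p = 0.00475). The thalamus and midbrain list shares Tcf7l2 with the list of oligodendrocyte lineage precursors, so it is not a measure of region alone. Of 28 respiratory chain genes 7 rose, Atp5e by 0.46 and Ndufa2 by 0.44 (14 adjusted over the list alone; list adjusted p = 0.422), and of 25 cytosolic ribosomal proteins 19 (24 adjusted over the list alone; list adjusted p = 0.286). Of 28 genes of GABAergic synapses and interneurons 3 rose, Npy, Cck and Sst by 0.28, 0.29 and 0.22, and 2 fell, Erbb4 by 0.31 among them (3 and 2 adjusted over the list alone; list adjusted p = 0.777). Of 35 genes of glutamatergic synapses 1 rose, Syp by 0.20, and 2 fell, Gria1 by 0.21 among them (2 and 3 adjusted over the list alone; list adjusted p = 0.745). In all 1238 genes were called, 806 higher and 432 lower. With the GC and length correction 512 were called, 353 of them shared, and without LPS-LPS replicate 3 297. Of the 26 ribosomal protein and respiratory chain genes called higher, 12 stayed called with that correction and 10 without that library. Other settings raised the total, to 1987 by DESeq2, 2185 with the replicate block, 2251 with the cerebellum covariate and 1981 without saline-LPS replicate 1. Median exonic length was 2308 bases for genes called higher, 8329 for genes called lower and 3863.5 for the rest. Log2 fold changes fell with exonic length (Spearman -0.531, and -0.528 in averaged prenatal LPS). Deviations of a library from the mean of all libraries correlated with length at 0.208 to 0.434 in saline-saline and -0.46 to -0.226 in LPS-LPS. Calls of short genes as higher and long genes as lower may therefore reflect this trend in part.

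Pubertal LPS was compared with saline 2 days before collection in the same prenatal background, to ask whether it differed by itself and whether prenatal LPS altered the response. After prenatal saline, no gene passed edgeR's test (0 called, 535 at an unadjusted p under 0.05 where 944 are expected, and 0 by DESeq2). Mbd2, a reader of DNA methylation, had a log2 value of -0.31 ± 0.07, Slc13a4, a sulfate transporter, 0.36 ± 0.09 and Slc9a4 -0.78 ± 0.19, each with an adjusted p of 1. Gfap, Lcn2 and Aif1 had 0.15, 0.19 and 0.08 (adjusted p = 1). After prenatal LPS, edgeR again called 0 (756 at an unadjusted p under 0.05), whereas DESeq2 called 9. Ftl1, the ferritin light chain, had 0.55 ± 0.10, Rn7sk 1.95 ± 0.36 and Rps28, a ribosomal protein, 0.59 ± 0.11, each with an adjusted p of 0.193. Gfap, Lcn2 and Aif1 had 0.07, -0.14 and 0.17 (adjusted p = 1). Averaged over prenatal treatment 0 were called (947 at an unadjusted p under 0.05, and 0 by DESeq2), with Etnppl at 0.37 ± 0.08, Mt3 at 0.25 ± 0.05 and Ftl1 at 0.33 ± 0.07 (adjusted p = 0.618). Gfap, Lcn2 and Aif1 had 0.11, 0.03 and 0.13 (adjusted p = 0.951, 0.996 and 0.966). Without saline-LPS replicate 1 the averaged comparison called 10 genes and the one after prenatal saline 3. Within libraries at 1 CPM of Gabra6 or more, a split chosen after seeing the data, the averaged comparison called 31 genes, 27 of them higher. Within those under 1 CPM it called 1.

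The interaction, which tests whether the response to pubertal LPS differed by prenatal exposure, called 0 genes in edgeR (402 at an unadjusted p under 0.05) and 1, Rps28, in DESeq2. Rps28 had a difference of 0.82 ± 0.16 and Gm4673 of 0.64 ± 0.13 (adjusted p = 0.887), and Mbd2 0.42 ± 0.09 (adjusted p = 1). Gfap, Lcn2 and Aif1 had -0.07, -0.33 and 0.10 (adjusted p = 1). Camera called 0 of 39 lists in any of these comparisons with an estimated correlation. The interaction test recovered 65% of simulated changes of 1 log2 unit and 22% of those of 0.5. The simulated counts lacked the structure of the real libraries, so the power in these data is not known. The cytokine genes Il1b, Tnf and Il6 stayed below the count filter. Il1b summed to 22, 25, 28 and 46 counts in saline-saline, LPS-saline, saline-LPS and LPS-LPS, Tnf to 9, 5, 0 and 6, and Il6 to 3, 4, 3 and 4.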

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

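Of 740 groups of 4 values tested with Dixon's ratio (gap over range, above its 95% critical value for 4 samples), 42 had a sample far from the others, and chance gives about 1 in 20. The test of replicate numbers was chosen after the result was seen. The prediction on the cerebellum was written before.

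Cerebellar transcripts stood apart in saline-saline replicate 4, whose Gabra6 (ratio 0.995, 44.4 CPM) and cerebellum list mean (0.927) were far above the other 3 libraries. Among the 17 other cerebellum markers tested, 7 were lower in the 8 libraries under 1 CPM of Gabra6 with no overlap, where chance gives 0.00777% per gene. Cbln3 averaged 0.65 against 56.3 CPM and Fat2 0.999 against 35.7 CPM, and the median difference over the 17 was 0.685. The bounds set in advance, more than 1 log2 unit or no overlap in most markers, were not reached. Overlapping markers such as Itpr1, Calb1 and Rgs8 still averaged 380, 117 and 118 CPM in the 8 libraries. Markers with so much signal there could hardly part the libraries, although Pcp4 and Barhl2 overlapped at 1.53 and 2.38 CPM. The missed bounds therefore do not argue against a cerebellum missing from the tissue. A missing cerebellum may be a cause but cannot be told apart from a partial change of these genes. The 8 libraries carried replicate number 1 or 2 in 7 cases against 1 of the other 8 (exact Fisher p = 0.0101), which is consistent with a shared collection round, and no association with either injection was found (exact Fisher p = 0.619 for each).

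LPS-LPS replicate 3 stood apart in Xist (ratio 0.99969, 503 CPM), Ddx3y (0.863, 0 CPM) and the sex-linked list mean (0.977). Xist had 15912 counts there, while the Y-linked Ddx3y, Kdm5d and Eif2s3y had 0 and Uty had 2. These values argue against a male mouse as the source of this library. A female mouse in this group and a swapped sample cannot be told apart. Pituitary transcripts stood apart in LPS-LPS replicate 1 for Gh (0.99987), Prl (1, 106 CPM) and the list mean (0.913), and in saline-LPS replicate 1 for Gh (0.942) and Prl (0.967). Prl was also apart in LPS-saline replicate 2 (1, 0.0777 CPM) and low in saline-saline replicate 4 (0.895). These rest on 3 and 0 counts, within counting error, against 3349 in LPS-LPS replicate 1 and 190 in saline-LPS replicate 1.

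Further values in saline-LPS replicate 1 were Laptm5 (0.937), Plekhg1 (0.899), Plekhh1 (0.856), Saa3 (1, 0.0938 CPM, only 3 counts), Slc1a2 (0.942) and the list means of NF-kB cytokines (0.89) and stress chaperones (0.857), all high, and Ndufa2 (0.885) and the lymphocyte list mean (0.841), both low. In LPS-LPS replicate 4 B2m (0.98), Ermn (0.856), Laptm5 (0.933) and the ependyma list mean (0.857) were low, as was Gjb6 in LPS-LPS replicate 2 (0.922).

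In LPS-saline, Saa3 was high in replicate 3 (0.845, 2.96 CPM), Enpp6 in replicate 4 (0.886) and Fgfr3 in replicate 1 (0.836), and Eomes was low in replicate 1 (0.888) and Etnppl and Uqcrq in replicate 2 (0.844 and 0.903). In saline-saline, H2-K1 (0.82903), Sphk1 (0.855) and Tnfaip2 (0.904) were high in replicate 2, Nfkbia (0.836) and Tsc22d3 (0.9003) in replicate 3, and Gjc3 in replicate 4 (0.923). Low values there were Ifi27 in replicate 4 (0.871), Lrrc58 (0.852) and the glutamatergic synapse list mean (0.871) in replicate 1, and the stress chaperone list mean in replicate 3 (0.838).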

How the results depend on the processing

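Corrections for GC content and length, the cerebellum covariate, their combinations and the split by Gabra6 were chosen after seeing the data, the other alternatives before. Over settings other than leaving out a library, 1834 of 2174 values kept direction and side of the threshold, and 4 reversed: C1ql1, prenatal LPS averaged over pubertal treatment, with the correction (log2 -0.0252), with the covariate added (-0.0315) and with the replicate block added (-0.0277), and Cox6a1, prenatal LPS averaged over pubertal treatment, with correction and covariate (-0.00743). The cause was not tested. For prenatal LPS before pubertal saline (34 called), 127 were called without a filter, 433 by DESeq2, 409 with the replicate block, 683 with a surrogate variable, 463 with the covariate, 101 with correction and covariate, 107 with correction and block, and 233 with the compared groups alone. For prenatal LPS before pubertal LPS (115) these were 178, 411, 326, 722 and 451, then 37 with the correction and 29 with the compared groups alone. For both exposures (1238), DESeq2 gave 1987, the block 2185, a surrogate variable 2726, the covariate 2251, the correction 512 and the compared groups alone 2271. For averaged prenatal LPS (1476) DESeq2 gave 2268, the block 2495, a surrogate variable 3188, the covariate 2705, the correction 639, and libraries under and over 1 CPM of Gabra6 27 and 996. For pubertal LPS after prenatal LPS (0), 4 were called without a filter, 9 by DESeq2, 7 with a surrogate variable or the compared groups alone, 1 with the covariate (Ftl1), 1 with the correction (Usmg5), 4 with both and 2 with correction and block (Ndufb8 and Ftl1), genes named after their values were seen. The interaction gave 1 by DESeq2, and averaged pubertal LPS 1 (Fos) and 31 within libraries under and over 1 CPM of Gabra6. Over all comparisons camera called 3 lists with an estimated correlation, 105 with a preset one, and fry 30; the MHC class I list for both exposures passed with the block (adjusted p = 0.0447), the correction (0.0319) and the covariate (0.0394). The replicate numbers did not pair libraries by the rule that every pair correlates over 0.1 for both exposures (0.0274 to 0.38) or pubertal LPS after prenatal saline (0.0737 to 0.383), although 3 of 4 pairs passed in each; 10 of 16 libraries correlated best with their own number.

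Leaving out each library gave 0 to 3 calls for pubertal LPS after prenatal saline (3 without saline-LPS 1), 0 to 2 after prenatal LPS (2 without LPS-saline 4, 1 without LPS-saline 1 or saline-LPS 1), 0 for the interaction, and 0 to 10 for averaged pubertal LPS (10 without saline-LPS 1). Prenatal LPS before pubertal saline ranged from 7 to 391: without saline-saline 1 to 4 it was 17, 18, 12 and 7, without LPS-saline 1 to 4 10, 17, 9 and 123, without saline-LPS 1 391, and 21 without LPS-LPS 1 or 2. Before pubertal LPS it ranged from 22 to 126: 75, 70 and 69 without saline-saline 1, 3 and 4, 63 without LPS-saline 3, 57 and 49 without saline-LPS 1 and 3, and 31, 22 and 41 without LPS-LPS 1, 3 and 4. Both exposures ranged from 297 to 1981: 388 and 365 without saline-saline 2 and 4, 1981 without saline-LPS 1, and 567, 297 and 605 without LPS-LPS 1, 3 and 4. Averaged prenatal LPS ranged from 700 to 1645: 931 and 846 without saline-saline 2 and 4, 700 without LPS-saline 1, and 917 and 736 without LPS-LPS 1 and 3. The list tests gave 4 calls without LPS-LPS 3.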

Other observations

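Tests of GC content and length, of microglia, of border macrophages and of the label order, and the counts of other splits for pairs of groups and of splits that part every pair, were chosen after the result was seen, as were the genes and lists named in the next paragraph. The microglia test replaced one run on called genes alone, whose outcome their selection had fixed.

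In LPS-LPS against saline-saline, genes of the meninges and fibroblasts rose in 8 of 18 cases, with Foxd1 at log2 0.85 ± 0.11 (adjusted p = 0.000729), Crabp2, a retinoic acid binding protein, at 0.77, and Slc6a13, a GABA transporter of the leptomeninges, at 0.51 (list adjusted p = 0.216 with an estimated correlation). Of 17 hypothalamic genes 3 rose, the neuropeptides Cartpt (0.47), Trh (0.45) and Npy (0.28), with a list adjusted p of 0.356. In the choroid plexus list 3 of 18 rose, among them the water channel Aqp1 (0.50), with a list adjusted p of 0.844. Ribosomal protein genes that rose included Rpl41 (0.48) and Rpl13 (0.33). Across libraries, the mean of border macrophage and monocyte genes was higher by 0.232 in prenatal LPS before pubertal saline, by 0.315 in both exposures and by 0.21 in pubertal LPS after prenatal saline, and that of olfactory bulb genes by 0.301 and 0.253 in the first and second of these. In both exposures the means of meninges and fibroblasts (0.336), hypothalamus (0.249) and cytosolic ribosomal proteins (0.345) were higher and that of thalamus and midbrain (-0.229) lower. The ribosomal mean was also higher in pubertal LPS after prenatal LPS (0.18) and in prenatal LPS before pubertal LPS (0.29). Each of these had an exact permutation p of 0.0286, the smallest this design allows, and 0.234 after adjustment over 90 tests, which so small a design could hardly pass.

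Of 114 tested genes in the MHC class I, interferon, complement and microglia activation lists, 44 were higher after prenatal LPS. A bias by GC content or length is argued against as the whole cause for these 44, since 34 stayed called with the correction. Their median log2 change was 0.526 before and 0.483 after. All 44 stayed above 0, but they were picked as rising in these same data, which nearly fixes their sign. The other members of the 114 are not covered by this. More microglia is argued against as the whole cause for MHC class I, whose tested members, called or not, rose by 0.467 ± 0.0608 (SE) more than the 20 homeostatic genes. This is less clear for interferon-stimulated genes (0.145 ± 0.0587). More microglia cannot be told apart for complement (0.0506 ± 0.0439) and microglia activation (0.0979 ± 0.0552), where the differences exceed their standard errors but lie within 2 of them. The homeostatic genes rose by 0.182 themselves (exact permutation p = 0.0186). More border macrophages or monocytes was tested in LPS-saline against saline-LPS only, and there it is argued against for MHC class I. This list was higher by 0.746 ± 0.0969 (SE) over the 8 border macrophage genes of at least 1 CPM (0.631 ± 0.116 over all 13). More narrowly, it is argued against there for interferon-stimulated genes (0.361 ± 0.0733, and 0.245 ± 0.0989 over all 13) and microglia activation (0.288 ± 0.0577 and 0.172 ± 0.061). For complement it cannot be told apart, since the margin depended on the border genes used (0.288 ± 0.0434, and 0.172 ± 0.0858 over all 13). The mean of all 13 was itself higher by 0.232 in prenatal LPS before pubertal saline and by 0.105 before pubertal LPS. Averaged, the mean of the 8 was higher by 0.0299. Whether the 44 genes rose beyond the border mean in averaged prenatal LPS was not tested. A reversed order of the label words cannot be told apart, because 0 genes were called for pubertal LPS and the names would only swap, and under it the same rise may be a response to an injection 2 days before collection, and with the order used a lasting difference after the dam's injection, or one between litters, which stays untested.

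In LPS-LPS, 26 of 53 ribosomal protein and respiratory chain genes were higher than in saline-saline. With the GC and length correction 12 stayed called, as the median log2 change went from 0.373 (quartiles 0.308 and 0.446) to 0.255 (0.151 and 0.342), so such a bias may account for part. Their median exonic length was 1640 bases against 3830 for tested genes. Without LPS-LPS replicate 3, 10 stayed called, the fewest for any library of both groups, which met the bound set in advance for a single library. That library may therefore account for part of the calls, but leaving out saline-saline replicate 4 or 2 also met it (11 and 12; 15 to 26 for the other 5), and the median without LPS-LPS replicate 3 was 0.348 with all 26 above 0, so it cannot be told apart from a loss of calls with fewer libraries.

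Other splits of the same libraries tested whether chance could give as many calls. These splits moved single mice, and litters are not given, so chance differences between litters cannot be excluded by them. Chance in the grouping of single mice can be excluded for averaged prenatal LPS (1476, 1 of 100 drawn, highest other 105). There 1 of 100 splits drawn from the 128 that part every pair of numbers called as many too (highest other 182). For both exposures (1238, 1 of 35, highest other 1) chance in the grouping of single mice can be excluded only if these libraries are taken as unpaired. However, 3 of their 4 pairs correlated over 0.1. The 8 splits that part every pair (highest other 1) are too few for a share under 0.05. For prenatal LPS before pubertal saline (34) 1 of 35 splits called as many (highest other 0), but the numbers were taken to pair these libraries. The 8 splits that part every pair (highest other 0) are too few for a share under 0.05. For prenatal LPS before pubertal LPS (115) chance was not excluded, since 2 of 35 splits called as many. The other one, with 1215 calls, put replicates 1 and 2 against 3 and 4, which points to a structure of the samples, while of the 8 splits that part every pair of numbers, again too few, the highest other was 0. For the comparisons with 0 calls the count tests nothing, since every split calls at least 0: 35 of 35 for pubertal LPS after prenatal saline (highest other 1628, again replicates 1 and 2 against 3 and 4) and after prenatal LPS (highest other 1), and 100 of 100 for the interaction (highest other 149) and averaged pubertal LPS (highest other 1).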
